A study of Mus musculus with 4 samples.

How the data were processed

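The data are single-cell RNA counts from mouse mammary tumours. Cells of 4T1, a BALB/c mammary carcinoma line, with intact Cd28 (Cd28+/+, called control here) or without it (Cd28−/−, called knockout here) were implanted orthotopically in female BALB/c mice. Per the labels' protocols, tumours were taken 6 or 10 days after implantation, cut up and digested with collagenases and DNase, red cells were lysed, CD45+ cells were sorted by flow cytometry, and Chromium single cell 3' libraries were made. There was 1 library for each of the 4 groups (control day 6, knockout day 6, control day 10, knockout day 10). How many mice went into a library is not given in the sources used here.

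For each library the authors deposited an unnormalized matrix of UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and cell barcode, with the gene identifiers and barcodes. The submitters' processing notes name Cell Ranger 2.1.1 and the mm10 build, while cellranger 5.0.0 stands in the matrices, per the file headers; which of these versions made the counts is not given in the sources used here. The matrices held the same 27998 genes, of which 20831 had at least 1 UMI. Of their identifiers, 27645 stood in the mouse gene annotation used here, and 121 genes with a symbol that occurs more than once were kept apart by identifier. The matrices held 12110 barcodes in control day 6, 11469 in knockout day 6, 10441 in control day 10 and 13366 in knockout day 10. Every library's smallest barcode had exactly 500 UMIs, so barcodes under that minimum had been left out before deposit. The median per barcode was 2694.5, 2733, 2452 and 2825 UMIs, in the same order.

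Barcodes with under 200 genes (35, 53, 26 and 38) or over 10% of UMIs from mitochondrial genes (294, 373, 166 and 264) were removed. Doublets were called in each library with Scrublet as run in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. It marked 366 (3.02%), 285 (2.48%) and 294 (2.20%) barcodes in control day 6, knockout day 6 and knockout day 10. In control day 10 its automatic threshold marked 0.00958%, under the 0.5% taken as the sign of a failed call, so the 872 highest scores (8.35%, the expected rate) were removed there instead. This left 11444, 10800, 9403 and 12801 cells, 44448 in all.

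Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without 136 mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, gave 30 principal components, a graph of 15 nearest neighbours and Leiden clusters at resolution 1.0 (igraph 0.11.9), over all 4 libraries without integration. Clusters of T and NK cells, and of macrophages, monocytes and dendritic cells, were clustered again in the same way, as were unnamed clusters without cell cycle genes. A cluster was named from 23 sets of marker genes when at least 3 markers of the set, each detected in at least 25% of its cells, stood among its top 25 genes by fold. A cluster stayed unnamed where more markers of another class than of its own stood among its top 10 genes, or where its median UMI count was, multiplied by 3, still under its sample's median, with no marker of its class in that top 10. Immunoglobulin and T cell receptor segment genes, Clec7a, Cxcl11, Mx2, Cd301b and Ahsp were not analysed here. Names of clusters are rebuilt from markers and are not the authors' own, so a class means cells resembling that type.

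With 1 library per group there is no spread between libraries. No p-value, standard error or number of changed genes was computed, and no difference has a replicate check. Shares of cells carry exact Clopper-Pearson 95% intervals, and ratios of shares carry the interval of a conditional binomial. For expression, UMIs were summed per library and class and given as CPM, that is, as counts relative to the class's total UMIs, with exact Poisson 95% intervals, and log2 ratios of CPM carry the exact conditional binomial interval. After the values were seen, the part of Cd274 that free RNA could give was estimated from the median level of neutrophil markers relative to all cells, and cell cycle medians were taken within clusters. All intervals cover counting error only, not differences between mice, tumours, sorts or library preparations. Classes with at least 50 cells in both libraries were compared, which left B cells and plasmacytoid dendritic cells of day 10 out. A barcode count of 0 was given with the upper limit that 3 counts allow.

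The 20 gene lists, the cell type markers, the filters, the rule for named genes and most alternatives were fixed before the data were examined. The lists were cytotoxicity, inhibitory receptors, naive and memory T cells, T cell costimulation, regulatory T cell effector genes, interferon gamma response, type I interferon response, inflammatory (M1-type) macrophage genes, alternative (M2-type) macrophage genes, suppressive neutrophil (PMN-MDSC) genes, immature neutrophil and granule genes, chemokines, MHC class II presentation, MHC class I presentation, dendritic cell maturation, hypoxia and glycolysis, cell cycle, dissociation and heat-shock response, T cell ligands on antigen-presenting cells, and mitochondrial oxidative phosphorylation. A list was summarised by the median log2 ratio of its members with at least 20 UMIs over both libraries, the number of members at or beyond 0.5 in each direction, and the percentile of that median among 10000 random lists of the same size drawn from genes within 50 ranks in mean expression. Which lists are reported for which class was chosen after their values were seen, and a list reported for knockout against control is given for both days where both could be computed.

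Named genes were taken by rule. For each day and main class (neutrophils, macrophages or monocytes, dendritic cells, T cells, NK cells, B cells) these were the 3 genes with the highest and the 3 with the lowest log2 ratio, ranked by the interval bound nearest 0. Such genes had at least 50 UMIs in both libraries together, at least 50 CPM in 1 of them, and a CPM of at least 0.1 of their highest in any class, as a guard against free RNA; the 136 genes above were left out. Further genes were up to 3 each way with a log2 ratio of at least 1 or at most −1 on both days, the 2 highest and 2 lowest between days in each genotype, Cd28, Cd274, Pdcd1 and Ptprc in every class, and up to 4 members of each reported list. The text gives a part of the genes this rule takes and leaves out some with shared 3' ends. For genes named, the share of 31-mers in the last 500 bases of their transcripts that also occur in transcripts of another gene was computed from the annotation. Reads of such genes could have been split or assigned otherwise. A share of at least 30%, a limit chosen after the values were seen, is printed beside the gene and marks its value as uncertain. Below that limit, shares were 26.6% for Ifitm1, 24.0% for Ifit3, 22.2% for Gbp4, 22.1% for Ldha, 21.1% for Gzmf and at most 19.8% (Mgl2) for the other genes searched.

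Agreement of the knockout to control ratios between days was described by Pearson and Spearman correlations across genes with at least 50 UMIs over the 4 libraries and 10 on each day.

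The expression step was tested on counts simulated from the day 10 means and totals, with counting error only and 200 genes altered. For macrophages or monocytes (11250 genes) the interval covered the true log2 ratio for 98.0%, 92.0%, 98.0% and 90.0% of genes altered by 1, −1, 2 and −2 and for 95.9% of the 11050 unaltered genes. For dendritic cells (6445 genes) these were 90.0%, 100.0%, 90.0% and 94.0%, and 95.3% of 6245. An altered list stood at percentile 100.0 in both, and 6.5% of 200 unaltered random lists fell outside percentiles 2.5 to 97.5. In the day 10 data 10 and 16 of 20 lists did. Their genes can move together, which was not simulated, so percentiles do not test change.

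Alternatives covered the cell filter, doublets, cluster resolution, cell naming, separate clustering of each library, thinning of cells to 1000 UMIs, the denominator of shares, scaling of class sums, averaging over cells, and minimum counts. Python 3.11.15 was used with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.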

Results

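CD28 is the costimulatory receptor of T cells, and the series title concerns CD28 inside cancer cells, PD-L1 (Cd274) and resistance to anti-PD-1. The design asks how immune cells that infiltrate 4T1 mammary tumours differ when the implanted tumour cells lack Cd28. CD45+ cells were sorted from tumours of control (Cd28+/+) and knockout (Cd28−/−) 4T1 cells on days 6 and 10 after implantation, with 1 library per group and hence no replicates. The 4 libraries held 57406792 UMIs (control day 6), 58324440 (knockout day 6), 39696362 (control day 10) and 86630331 (knockout day 10). After filtering, 11444, 10800, 9403 and 12801 cells remained. Intervals below are 95% and cover counting error only, and every ratio is knockout over control unless a comparison of days is named.

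The knockout was made in the implanted tumour cells, whereas the CD45 sort takes immune cells, so Cd28 (ENSMUSG00000026012) in the immune classes does not check it. T cells carried Cd28 at 294 CPM (283 to 305) in control day 6, 289 (278 to 301) in knockout day 6, 297 (286 to 309) in control day 10 and 225 (217 to 233) in knockout day 10. NK cells held 125, 119, 175 and 92.7 CPM of Cd28 in the same order. Epithelial-like cells, which came through the CD45 sort and carried Krt8 and Krt18, held 1, 13, 14 and 22 Cd28 UMIs, or 0.697, 5.36, 3.97 and 1.97 CPM, and macrophages or monocytes, which should lack the gene, held 3.46, 4.41, 3.46 and 1.97 CPM. At this depth Cd28 in the epithelial-like cells stood at or near that background in every library.

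Cd274 (ENSMUSG00000016496), which encodes PD-L1, was most abundant in neutrophils. There it stood at 3195 CPM (3146 to 3244) in control and 3143 (3069 to 3217) in knockout on day 6, and at 2067 (2003 to 2133) and 2833 (2792 to 2875) on day 10. Macrophages or monocytes held 605 and 605 CPM on day 6 and 318 and 312 on day 10, so their log2 ratios were 0.00 (−0.04 to 0.04) and −0.03 (−0.08 to 0.03). Cd274 in dendritic cells was 419 and 415 CPM on day 6 and 217 and 368 on day 10. T cells held 144, 161, 121 and 164 CPM. Epithelial-like cells held 87.1 (72.5 to 104) and 77.5 (66.8 to 89.4) CPM of Cd274 on day 6, and 49.96 (42.9 to 57.9) in control and 30.8 (27.6 to 34.2) in knockout on day 10. Free RNA, at the level of neutrophil markers in these cells, could give 19.8%, 15.9%, 34.2% and 73.1% of these 4 values. On day 10 cluster 15 (median 1122 UMIs) held 53.3% of control and 27.0% of knockout epithelial-like cells, and cluster 22 (22550 UMIs) the others. Pdcd1 (ENSMUSG00000026285), which encodes PD-1, was close between the genotypes on day 6, at 129 CPM (121 to 136) in control and 112 (105 to 120) in knockout T cells, and was 332 (320 to 344) and 680 (667 to 694) on day 10. In CD8 T cells Pdcd1 stood at 148 and 127 CPM on day 6 and at 410 and 768 on day 10. NK cells held 8.42, 11.9 (18.3 in cells with at least 500 genes), 40.4 and 160 CPM. Macrophages or monocytes held 0.659, 0.697, 1.88 and 4.01.

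**Figure D1:**
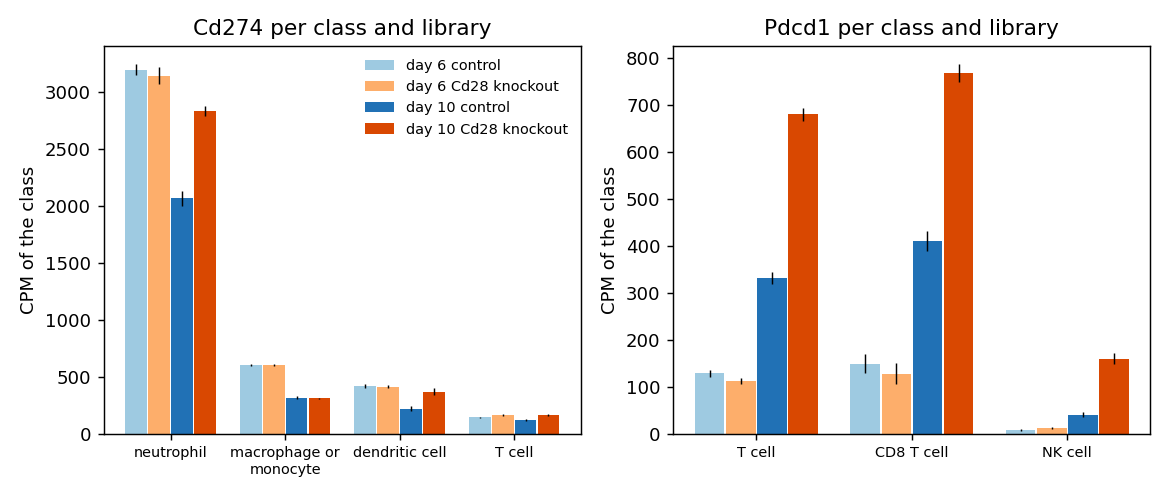
CPM of Cd274 and of Pdcd1, on separate linear axes, per cell class (horizontal axis) and library (colour), with exact Poisson 95% intervals as black lines. Cd274 stood highest in neutrophils, between 2067 and 3195 CPM, and Pdcd1 in T cells was 332 CPM in control and 680 CPM in knockout on day 10.

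On day 6, the knockout library held a smaller share of neutrophils and larger shares of mast cells or basophils and plasmacytoid dendritic cells than the control library, while dendritic cells and T cells were nearly level once neutrophils were left out. Neutrophils made up 13.8% of knockout and 24.9% of control cells, a ratio of 0.555 (0.521 to 0.591). Mast cells or basophils were 9.39% and 6.14%, a ratio of 1.53 (1.39 to 1.69), and plasmacytoid dendritic cells 1.98% and 1.26%, a ratio of 1.57 (1.27 to 1.96). Dendritic cells had a ratio of 1.24 (1.10 to 1.39) and T cells 1.18 (1.10 to 1.25), but among cells other than neutrophils these were 1.08 (0.955 to 1.22) and 1.03 (0.962 to 1.09), with 1.33 for mast cells or basophils and 1.37 for plasmacytoid dendritic cells. B cells had a ratio of 0.870 (0.768 to 0.985) and NK cells 1.05 (0.988 to 1.12; 0.919 among cells other than neutrophils). Macrophages or monocytes had a ratio of 1.14 (1.08 to 1.2), but 0.993 among cells other than neutrophils, 1.00 with each cell named on its own and 0.805 with each library clustered on its own. Within T and NK cells, regulatory T cells (Foxp3+ suppressors of immune responses) were 8.43% in knockout and 6.99% in control, a ratio of 1.2 (1.02 to 1.42), while CD8 T cells (5.75% and 6.05%) had a ratio of 0.951 (0.787 to 1.15), CD4 T cells 1.05 (0.969 to 1.14; 0.851 and 0.918 at resolutions 0.5 and 2.0), gamma-delta T cells 1.25 (0.946 to 1.66; 0.913 at resolution 2.0) and NK cells 0.961 (0.900 to 1.03). The CD8 ratio was 0.597 without a cell filter and 0.623 with doublets removed at the expected rate in every library. Shares depend on the CD45 sort and on the minimum of 500 UMIs per barcode. Among the named classes neutrophils, with a median of 1638.5 UMIs in control and 1303 in knockout, lie closest to that minimum.

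On day 10 the neutrophil ratio stood the other way, and NK cells, B cells, plasmacytoid dendritic cells and dendritic cells made up smaller shares of the knockout library. Neutrophils were 28.6% of knockout and 11.6% of control cells, a ratio of 2.47 (2.31 to 2.65). NK cells, innate killers of tumour cells, were 6.92% and 17.6%, a ratio of 0.393 (0.362 to 0.427). B cells were 34 of 12801 cells in knockout and 141 of 9403 in control, a ratio of 0.177 (0.118 to 0.259). Plasmacytoid dendritic cells had a ratio of 0.167 (0.0973 to 0.274; 0.297 with each cell named on its own), and dendritic cells 0.559 (0.466 to 0.668). Among the dendritic subclusters, cDC2-like cells were 0.172% of knockout and 1.40% of control cells, but cDC1-like cells 0.648% and 0.744% and mature ones 0.523% and 0.521%. Mast cells or basophils had a ratio of 0.735 (0.640 to 0.843), but 0.910 (0.793 to 1.04) among cells other than neutrophils. Their cluster 0, led by Mcpt8, held 183 cells in control and 0 in knockout. Barcodes with at least 3 Mcpt8 UMIs were 131 and 28. Cluster 24, led by Mcpt1, held 234 and 417. T cells were 20.1% and 24.8%, a ratio of 0.812 (0.767 to 0.859), but 1.01 among cells other than neutrophils. Macrophages or monocytes as a joint class were 30.4% and 29.7%, a ratio of 1.02 (0.973 to 1.07), but 1.27 among cells other than neutrophils, 1.45 with cells thinned to 1000 UMIs and 0.949 with each library clustered on its own. Within macrophages, monocytes and dendritic cells, monocyte-like cells were 3.60% in knockout and 20.8% in control, a ratio of 0.174 (0.144 to 0.208; 0.356 with each library clustered on its own). On day 6 they were 25.9% and 23.2% (1.12, 1.01 to 1.24; 0.898 with doublets removed at the expected rate, 0.990 without a cell filter and 0.991 with each library clustered on its own). Subclusters without a name held 34.3% and 19.6% of these cells on day 10.

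Within T and NK cells of day 10, CD8 T cells were 26.2% in knockout and 16.5% in control, a ratio of 1.59 (1.43 to 1.76). Regulatory T cells were 10.9% and 5.07%, a ratio of 2.15 (1.81 to 2.56), and NK cells 20.8% and 36.1%, a ratio of 0.575 (0.525 to 0.629; 0.286 at cluster resolution 2.0). CD4 T cells had a ratio of 0.905 (0.823 to 0.995), but 1.04 and 1.03 at resolutions 0.5 and 2.0, and gamma-delta T cells 1.05 (0.848 to 1.30). Epithelial-like cells were 0.559% and 0.880% of control and knockout cells on day 6 (ratio 1.57, 1.13 to 2.19) and 3.21% and 4.89% on day 10. The day 10 ratio was 1.52 (1.33 to 1.75), but 1.16 with doublets kept, 1.21 with doublets removed at the expected rate in every library and 1.14 with each cell named on its own. Unnamed cells were 4.39%, 4.12%, 3.19% and 3.70% over the 4 libraries. The median UMI count on day 10 was 2154 per macrophage or monocyte in control against 7984 in knockout, but 3005 and 3988.5 per T cell and 1548 and 1613 per neutrophil. With the UMI minimum of the knockout library raised 3.71 times, as in macrophages or monocytes, the neutrophil ratio was 1.46 (1.35 to 1.58).

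**Figure D2:**
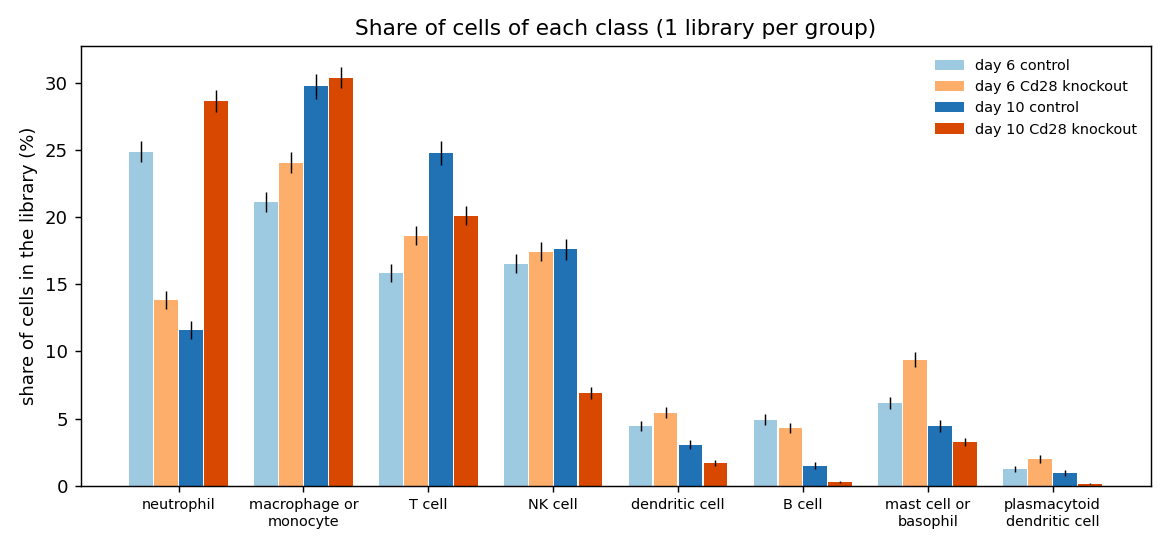
Share of cells (%) of each class (horizontal axis) in the 4 libraries (colour), with exact Clopper-Pearson 95% intervals as black lines. Neutrophils were 24.9% of control and 13.8% of knockout cells on day 6, and 11.6% and 28.6% on day 10.

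Within cell classes on day 6, knockout tumours held macrophages with higher cell cycle and lower type I interferon genes, and T and NK cells with lower granzyme and perforin transcripts, the T cells also with lower inhibitory receptor transcripts. Most list medians lay within 0.5 on the log2 scale. In macrophages or monocytes, 22 of 34 cell cycle genes were higher by at least 0.5 and none lower (median log2 ratio 0.55, percentile 100 among random lists of like expression), among them Birc5 (1.56-fold) and Top2a (1.45-fold). Of 29 type I interferon response genes, which are induced by antiviral interferons, 13 were at or below −0.5 and none at or above 0.5 (median −0.47, percentile 0.0). Ifit1 was 2.03-fold, Ifit2 1.80-fold and Irf7 1.62-fold lower.

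The largest ratios in day 6 macrophages or monocytes were those of Flt1, a VEGF receptor (2.77-fold higher), the metallothionein Mt2 (2.71-fold) and Clec12a (1.92-fold). Lowest were Retnla, a marker of alternative activation (5.67-fold lower; log2 −2.5, −2.69 to −2.32), the collagenase Mmp13 (5.02-fold) and the fatty acid carrier Fabp5 (ENSMUSG00000027533; 3.17-fold). Alternative (M2-type) macrophage genes had a median of −0.20 (2 of 19 higher, 4 lower; percentile 0.02) and inflammatory (M1-type) macrophage genes −0.18 (1 of 17 higher, 3 lower; percentile 0.09), with Nos2 2.31-fold lower (log2 −1.21, and −0.59 as a mean over cells). Chemokines had a median of −0.23 (4 of 21 higher, 5 lower; percentile 0.0), with Pf4 1.96-fold lower and the T cell attractant Cxcl9 1.53-fold higher. Medians were 0.17 for the interferon gamma response (4 of 30 higher, 2 lower; percentile 99.97), 0.20 for MHC class II presentation (1 of 15 higher, none lower), and 0.15 for mitochondrial oxidative phosphorylation (none of 21 beyond 0.5). Hypoxia and glycolysis (−0.02; 1 of 26 higher, 2 lower) and the dissociation and heat-shock response (0.08; 1 of 23 higher, none lower) lay near 0. Cluster 14, whose leading genes include Fabp5 and Pf4, held 15.3% of control and 7.74% of knockout cells of this class. On reclustering, subcluster M7, whose leading genes include Fabp5, Pf4 and Mmp13, held 59 and 9 cells.

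In day 6 neutrophils, scaling to the total put the median gene 0.24 (log2) above that from median-of-ratios scaling, so single genes are given relative to this shift. Granule genes of immature neutrophils were lowest: Camp (ENSMUSG00000038357), an antimicrobial peptide, at −3.18 (−3.63 to −2.75), Ngp (ENSMUSG00000032484) at −2.56 (−2.82 to −2.30) and Ltf, lactoferrin, at −2.05 (−2.41 to −1.70). As means over cells these were, unshifted, −1.84, −1.53 and −0.52. Highest were Usp7 (1.33), the inhibitory lectin receptor Clec12a (1.04) and Klhl6 (1.01). Before the shift, 4 of 14 immature neutrophil and granule genes were lower by at least 0.5 and none higher (median −0.17, percentile 0.06; −0.41 relative to the shift). Type I interferon response genes had a median of −0.28 (2 of 27 higher, 2 lower; −0.51 relative to the shift), suppressive neutrophil (PMN-MDSC) genes −0.14 (1 of 23 higher, 2 lower; −0.37) and hypoxia and glycolysis −0.25 (2 of 25 lower, none higher; −0.49). Isg20 stood at −0.82 and the glycolytic Eno1, which shares 42.9% of its 3' end sequence with other genes, at −0.87. Dissociation and heat-shock genes had a median of 0.29 (7 of 23 higher, none lower; 0.06 relative to the shift), with Hsp90aa1 at 0.51 (46.1% of its 3' end shared). Cluster 2 held 69.4% of control and 66.2% of knockout neutrophils and cluster 3 15.6% and 24.1%. Cluster 4, with Isg20 and Ifit1, held 13.2% and 9.60%, and cluster 21, with Rsad2, 50 and 1 cells.

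Dendritic cells of day 6, 76.0% of them in cluster 5 in control and 80.3% in knockout, differed in the chemokine Ccl17 (ENSMUSG00000031780), which attracts CCR4+ T cells and was 2.83-fold higher in knockout (log2 1.5, 1.35 to 1.65). The nuclease Dnase1l3 was 2.88-fold higher (log2 0.82 with each cell named on its own) and Cxcl9 1.56-fold. Lower were Ifitm6 (3.37-fold), AY761185 (3.03-fold) and Timp1 (ENSMUSG00000001131), an inhibitor of metalloproteinases (2.38-fold; log2 −0.45 with each cell named on its own). The median of type I interferon response genes was −0.28 (6 of 29 lower, none higher; percentile 0.0), with Irf7 1.68-fold lower. The other medians were 0.10 for the interferon gamma response (5 of 30 higher, 1 lower), 0.00 for dendritic cell maturation (1 of 20 higher, 1 lower), 0.09 for MHC class I presentation (1 of 22 higher, none lower), 0.16 for MHC class II presentation (none of 15 beyond 0.5), −0.03 for T cell ligands on antigen-presenting cells (1 of 14 higher, 2 lower), 0.23 for hypoxia and glycolysis (3 of 26 higher, none lower) and −0.03 for the dissociation and heat-shock response (none of 23 beyond 0.5; 0.031 as a mean over cells).

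T cells of day 6 held less RNA of killing molecules and inhibitory receptors in the knockout library. Of 18 cytotoxicity genes, 7 were lower by at least 0.5 and 1 higher (median −0.33, percentile 0.0), with perforin (Prf1) 2.31-fold and granzyme B (Gzmb, ENSMUSG00000015437) 1.97-fold lower. The exception, Gzmd, 37.7% of whose 3' end is shared, was 1.83-fold higher, but it stood at −5.55 (log2) in cells with at least 500 genes, −4.00 with each cell named on its own, −4.72 with doublets removed at the expected rate and −0.37 as a mean over cells. Of 14 inhibitory receptors, 5 were lower and none higher (median −0.38, percentile 0.0), among them Havcr2 (1.62-fold), Lag3 (1.61-fold) and Tigit (1.49-fold), while Pdcd1 stood at −0.20 (−0.32 to −0.07). Other T cell medians were −0.15 for the type I interferon response (2 of 29 higher, 2 lower), −0.02 for naive and memory T cells (1 of 12 each way), −0.14 for T cell costimulation (none of 12 beyond 0.5), −0.14 for hypoxia and glycolysis (2 of 25 higher, 1 lower) and −0.05 for the dissociation and heat-shock response (1 of 23 higher, none lower). Cell cycle genes had a median of −0.12 (2 of 34 lower, none higher), but 0.053 with doublets kept, 0.015 with each cell named on its own and 0.39 with doublets removed at the expected rate. Cluster 7 held 60.2% of control and 62.8% of knockout T cells. Cluster 12, with Pdcd1 and Lag3 among its leading genes, held 12.04% and 7.96%.

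Among day 6 CD8 T cells, 22 of 33 cell cycle genes were lower and 1 higher (median −0.93), with Rrm2, a ribonucleotide reductase subunit, 3.97-fold and Mki67 2.54-fold lower. With doublets kept, however, the median was −0.19, Rrm2 stood at −0.87 in place of −1.99 and Mki67 at −0.11 in place of −1.35, and with each cell named on its own the median was −0.15. Naive and memory genes had a median of 0.43 (5 of 12 higher, none lower), with Tcf7 1.76-fold and Bcl2 1.81-fold higher. With doublets removed at the expected rate that median was −0.52, Tcf7 stood at −0.81 and Bcl2 at 0.10, and with each cell named on its own the median was −0.10. The median log2 ratio of inhibitory receptors in CD8 T cells, day 6, was −0.38 (2 of 12 higher, 4 lower), with Tigit 1.80-fold, Lag3 1.72-fold and Havcr2 1.68-fold lower and Pdcd1 at −0.22 (−0.54 to 0.10; 0.47 with doublets kept). With doublets removed at the expected rate it was 0.28, with Lag3 at 0.48 and Havcr2 at −0.05. Cytotoxicity had a median of −0.15 (3 of 17 higher, 4 lower), T cell costimulation −0.34 (3 of 12 lower, none higher; −0.086 with each cell named on its own and −0.052 with doublets removed at the expected rate) and the type I interferon response 0.03 (3 of 22 higher, 2 lower; 0.47 with doublets kept and −0.43 with each cell named on its own). CD4 T cells had medians of −0.46 for inhibitory receptors (7 of 14 lower, 1 higher), with Havcr2 1.64-fold and Tigit 1.61-fold lower, and −0.27 for regulatory T cell effector genes (4 of 16 lower, 1 higher), with Il10 2.5-fold lower (log2 −0.12 as a mean over cells). In regulatory T cells, medians were −0.07 for regulatory T cell effector genes (2 of 16 lower), 0.10 for the interferon gamma response (2 of 25 higher; −0.022 with each cell named on its own), −0.19 for the type I interferon response (2 of 26 higher, 5 lower) and −0.04 for the dissociation and heat-shock response (1 of 23 each way). Gamma-delta T cells had medians of 0.02 for the interferon gamma response (2 of 26 higher, 4 lower) and 0.53 for the cell cycle (17 of 30 higher, 1 lower; −0.12 in cells with at least 500 genes).

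NK cells of day 6 were lower in granzymes in the knockout library. Gzmf (ENSMUSG00000015441) was 8.17-fold lower (log2 −3.03, −3.37 to −2.71; −2.19 as a mean over cells), Gzme 3.35-fold (log2 −1.74, and −0.86 in cells with at least 500 genes; 45.5% of its 3' end shared), Gzmd 2.35-fold (log2 −1.23, and −0.43 in cells with at least 500 genes; 37.7% shared), Gzmb 1.69-fold and Prf1 1.37-fold. Cytotoxicity genes had a median of −0.24 (4 of 18 lower, none higher; percentile 0.0) and type I interferon response genes −0.51 (14 of 27 lower, none higher; percentile 0.0). Cell cycle (0.16; 1 of 34 higher), hypoxia and glycolysis (−0.06; 1 of 25 higher) and the dissociation and heat-shock response (−0.10; 1 of 23 lower) lay near 0. Highest were H2-Q7 (1.86-fold), Spry2 (1.76-fold) and Gm26917 (1.65-fold). In B cells, hypoxia and glycolysis had a median of −0.37 (2 of 25 higher, 8 lower; percentile 0.02; −0.031 with each cell named on its own), with Hilpda, a lipid droplet protein, 2.35-fold lower (log2 −0.53 with doublets removed at the expected rate). St3gal1 was 2.41-fold, Plac8 1.77-fold and Chst3 1.84-fold higher, and BC035044 2.99-fold lower.

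On day 10, macrophages of knockout tumours carried far more cell cycle RNA, type I interferon genes were lower in macrophages, T cells and NK cells, and glycolysis genes were higher in every main class compared. T and NK cells held more RNA of granzymes C and F and of Pdcd1 and less of Ccl5 or of genes of resting lymphocytes. In macrophages or monocytes, 33 of 34 cell cycle genes were higher by at least 0.5 and none lower (median 2.84, percentile 100; 1.98 as a mean over cells). A cluster of 4 control and 297 knockout cells (7.64% of this class), with C1qa and cell cycle genes among its leading genes and a median of 22831.5 UMIs, for which doublets were not excluded, held a part of this. Without it the median was 1.95, and within clusters it was 1.46 in cluster 14 and 1.51 in cluster 8, but −0.15 and 0.03 in the monocyte-like clusters 1 and 23. Ube2c (ENSMUSG00000001403), which drives mitotic exit, was 14.7-fold higher (log2 3.88, 3.57 to 4.21; 2.52 as a mean over cells) and Birc5 (ENSMUSG00000017716), which encodes survivin, 13-fold (log2 3.70, and 2.14 as a mean over cells). Of 29 type I interferon response genes, 28 were at or below −0.5 (median −1.46, percentile 0.0). Slfn5 (ENSMUSG00000054404) was 5.89-fold lower (log2 −2.56, and −1.75 as a mean over cells), Mx1 (ENSMUSG00000000386) 4.90-fold (log2 −2.29, and −1.67) and Ifit3 4.61-fold. Different clusters held most of the class in the 2 libraries, cluster 14 with 51.7% of control and 28.5% of knockout cells and cluster 8, with Trem2 and Stab1 among its leading genes, with 10.1% and 51.4%. Monocyte-like cluster 1 held 18.2% and 8.38%. Monocyte-like subcluster M0, with Hp, Slfn5, Mx1 and Ifit3 among its leading genes, held 182 and 47 cells.

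Alternative (M2-type) macrophage genes had a median of 0.50 in these day 10 macrophages or monocytes (9 of 19 higher, 5 lower; percentile 99.9), with the lectin Mgl2 (ENSMUSG00000040950) 10.3-fold higher (log2 3.37, 3.16 to 3.58; 2.70 as a mean over cells), Il10, which encodes an anti-inflammatory cytokine, 3.39-fold, the scavenger receptor Stab1 2.73-fold and Trem2 1.89-fold. Inflammatory (M1-type) macrophage genes had a median of 0.27 (6 of 17 higher, 2 lower; percentile 95), chemokines 0.19 (8 of 23 higher, 4 lower; percentile 78.4) and MHC class II presentation 0.27 (4 of 15 higher, 1 lower; percentile 92.2). Hypoxia and glycolysis had a median of 0.66 (17 of 26 higher, 1 lower), with Tpi1 1.97-fold and Eno1, whose 3' end is 42.9% shared, 1.98-fold higher, and mitochondrial oxidative phosphorylation 0.35 (7 of 21 higher, none lower). The interferon gamma response had a median of −0.31 (12 of 30 lower, none higher; percentile 0.01), with the immunity GTPase Irgm1 2.17-fold lower. Dissociation and heat-shock genes, a sign of tissue handling, had a median of −0.78 (1 of 23 higher, 16 lower), with Jun 3.85-fold lower (log2 −1.94, and −1.07 as a mean over cells). Also lower were haptoglobin, Hp (11-fold; log2 −3.46, and −2.13 as a mean over cells), Tmem176b (10.9-fold), and Fabp5 (2.08-fold; lower on both days). Monocyte-like cluster 23, with Hp among its leading genes, held 456 control and 92 knockout cells, and those with Tmem176b held 100 and 5 (cluster 27) and 188 and 28 (subcluster M9).

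**Figure D3:**
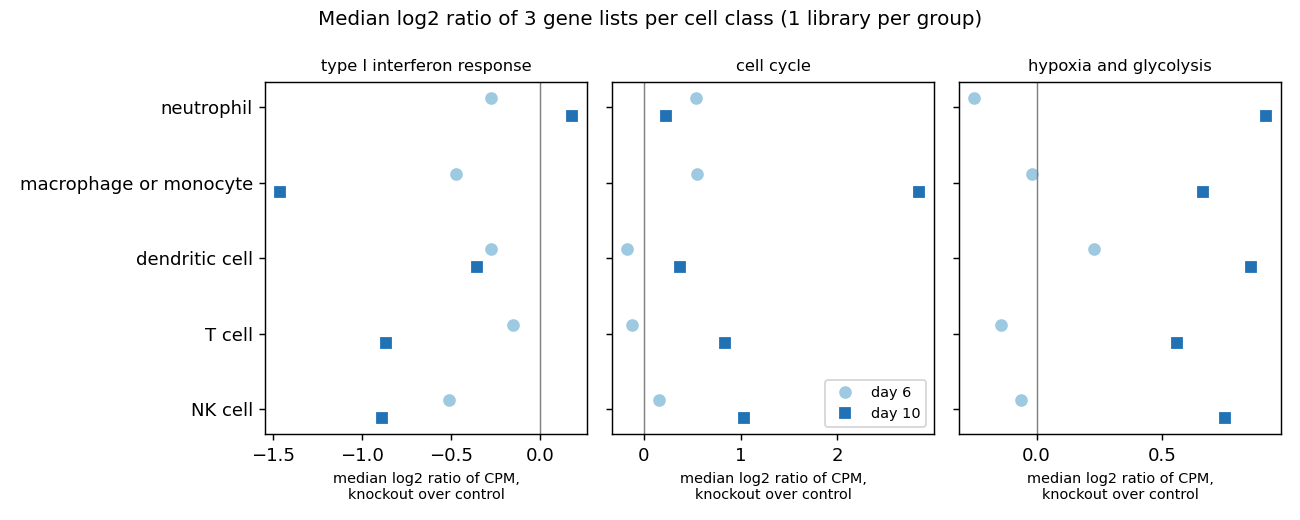
Median log2 ratio (knockout over control) of 3 gene lists, each with its own horizontal scale, by cell class on day 6 (circles) and day 10 (squares), before any shift for scaling and without error bars since there was 1 library per group. In macrophages or monocytes the cell cycle list stood at 0.55 on day 6 and 2.84 on day 10, and the type I interferon response list at −0.47 and −1.46.

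Day 10 neutrophils of knockout tumours were higher in glycolysis genes and lower in the granule genes Camp and Ngp. Scaling put the median gene −0.40 (log2) from that of median-of-ratios scaling, so single genes are given relative to this shift. Of 26 hypoxia and glycolysis genes, 18 were higher by at least 0.5 and none lower before the shift (median 0.91, percentile 100; 1.31 relative to the shift). Tpi1 (ENSMUSG00000023456), triose phosphate isomerase, stood at 2.04 (1.90 to 2.17), Ero1l at 1.90, Ldha at 1.79 and Ciart at 1.98, with 30.6% of its 3' end shared. Camp stood at −1.90 (−2.11 to −1.70), Ngp at −1.60 (−1.74 to −1.46), Ltf at −0.50 and Ly6g at −0.57, and immature neutrophil and granule genes had a median of −0.61 before the shift (1 of 14 higher, 8 lower; percentile 0.04) and −0.22 relative to it. Suppressive neutrophil (PMN-MDSC) genes had a median of 0.28 (5 of 24 higher, 1 lower; 0.68 relative to the shift), with Wfdc17 at 1.28, Ifitm1 at 1.30, Cd274 at 0.85 and Tgfb1 at −0.49. Type I interferon response genes had a median of 0.18 (7 of 27 higher, 4 lower; 0.58), with Ifit1 at 1.38, Usp18 at 1.26, Cmpk2 at 1.21 and Ifi27l2a at −0.64, and the interferon-induced chemokine Cxcl10 stood at 1.53. Dissociation and heat-shock genes had a median of −0.35 (3 of 23 higher, 9 lower), but 0.05 relative to the shift. Cluster 3 held 41.4% of control and 32.9% of knockout neutrophils. Cluster 4, with Ifit1, Usp18, Cmpk2 and Ciart among its leading genes, held 23.3% and 49.1%.

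Dendritic cells of day 10 were higher in MHC class I presentation and maturation genes in the knockout library. Medians were 0.62 for MHC class I presentation (14 of 22 higher, none lower), 0.60 for dendritic cell maturation (11 of 20 higher, 1 lower) and 0.59 for the interferon gamma response (16 of 27 higher, none lower), each at percentile 100, whereas MHC class II presentation stood at 0.12 (3 of 15 higher, 1 lower; percentile 90.5; −0.12 with each cell named on its own). The proteasome subunit Psmb9 was 2.46-fold higher (log2 1.30, and 0.63 as a mean over cells), the peptide transporter Tap1 2.29-fold, Il12b, an interleukin 12 subunit, 3.90-fold (log2 1.96, and 2.72 as a mean over cells), Iigp1 3.24-fold and Gbp4 3.14-fold (log2 1.65, and 0.77 with each cell named on its own). Ccl17 was 30.1-fold higher on 4 and 100 UMIs (log2 4.91, 3.51 to 6.82), and thus higher on both days, Ccl22 5.26-fold and Actn1 5.23-fold. T cell ligands on antigen-presenting cells had a median of 0.40 (6 of 12 higher, 3 lower), with Pdcd1lg2, which encodes PD-L2, 2.39-fold higher, and hypoxia and glycolysis 0.85 (19 of 25 higher, 1 lower), with Tpi1 3.86-fold higher (log2 1.95, and 1.36 as a mean over cells). Genes of the type I interferon response had a median of −0.35 (4 of 28 higher, 11 lower), with Ifi27l2a 3.73-fold lower (log2 −1.90, and −1.08 with each cell named on its own). The lectins Cd209e (22.9-fold) and Cd209a (ENSMUSG00000031494; 11.3-fold) were lower, as were Timp1 (4.34-fold; lower on both days) and Mrc1 (8.78-fold; log2 −3.13, and −0.55 with each cell named on its own). Dissociation and heat-shock genes had a median of −0.46 (1 of 23 higher, 11 lower; percentile 0.0). Cluster 5 held 81.3% of control and 63.9% of knockout dendritic cells. Cluster 6, mature dendritic cell-like and led by genes that include Ccl22 and Ccl17, held 18.8% and 36.1%. On reclustering, the cDC2-like subcluster, led by genes that include Cd209a and Cd209e, held 132 control and 22 knockout cells.

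T cells of day 10 held 12.4-fold more Gzmc (ENSMUSG00000079186), granzyme C, in the knockout library (log2 3.64, 3.54 to 3.74; 2.75 with each cell named on its own), 4.65-fold more Gzmf and 5.57-fold more Ccl1. Inhibitory receptors had a median of 0.44 (6 of 14 higher, 1 lower; percentile 100), with Pdcd1 2.05-fold and Tnfrsf9 1.74-fold higher. Cell cycle genes had a median of 0.84 (29 of 34 higher, none lower), with Ube2c 2.21-fold and Mki67 1.77-fold higher, and hypoxia and glycolysis 0.56 (15 of 26 higher, 2 lower), although Gapdh, whose 3' end is 45.0% shared, was 2.14-fold lower. Type I interferon response genes had a median of −0.87 (20 of 28 lower, 1 higher; percentile 0.0), or −0.67 over the 9 members whose level in T cells reached 0.1 of their highest in any class. Naive and memory T cell genes had a median of −0.48 (6 of 12 lower, 1 higher; percentile 0.0), with S1pr1, needed for exit from tissue, 3.53-fold lower (log2 −1.82, and −0.82 as a mean over cells) and Klf2 2.52-fold. Costimulation had a median of −0.35 (2 of 12 higher, 3 lower), with Cd28 1.32-fold lower, cytotoxicity 0.01 (5 of 18 higher, 6 lower) and the dissociation and heat-shock response −0.31 (7 of 23 lower, none higher; percentile 0.0). The ligand Cd70 was 5.45-fold higher and Il5 48.1-fold lower (log2 −5.59, −3.73 as a mean over cells and −0.71 with each cell named on its own). Gm28727 (11.2-fold lower) is uncertain as a predicted gene whose 3' end was not searched. Cluster 7, led by Tcf7, held 47.5% of control and 24.5% of knockout T cells, cluster 25, with Pdcd1 among its leading genes, 25.9% and 32.1%. Cluster 12, with Pdcd1, Ccl1 and Cd70, held 8.93% and 16.02%.

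In day 10 CD8 T cells, Gzmc was 9.35-fold (log2 3.23, and 2.1 with doublets removed at the expected rate) and Gzmf 3.86-fold higher in the knockout library, while Ccl5 (ENSMUSG00000035042) was 6.54-fold and Ifng 2.94-fold lower. Cytotoxicity had a median of −0.48 (3 of 18 higher, 8 lower), naive and memory genes −0.79 (1 of 12 higher, 9 lower), with Satb1 1.68-fold and Il7r 1.57-fold lower, and costimulation −0.58 (1 of 12 higher, 7 lower), although Tnfrsf4 was 2.39-fold higher. Cell cycle genes had a median of 0.69 (24 of 34 higher), with Cdk1 2.71-fold higher, inhibitory receptors 0.20 (4 of 14 higher, 2 lower; percentile 94.9), with Pdcd1 1.87-fold higher, and the type I interferon response −1.09 (21 of 25 lower; −2.23 with doublets removed at the expected rate). The transcription factor Ikzf2 was 2.48-fold higher. These cells lay in different subclusters. T4, with Gzmf, Pdcd1, Havcr2 and Lag3 among its leading genes, held 292 of 658 control and 776 of 906 knockout cells, and T10, with Ly6c2 and Tcf7, held 366 and 130. CD4 T cells had medians of 0.32 for inhibitory receptors (4 of 13 higher, 1 lower), with Pdcd1 2.14-fold and Tnfrsf9 2.07-fold higher, and 0.53 for regulatory T cell effector genes (8 of 15 higher, 4 lower), with Ebi3 3.0-fold and Ccr8 2.63-fold higher, and Cd83 was 5.91-fold higher. Their subclusters differed too. T5, with Ccl1, Ebi3, Ccr8 and Tnfrsf4 among its leading genes, held 200 of 994 control and 359 of 781 knockout cells, while T6 held 386 and 162 and T0 408 and 260.

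Regulatory T cells of day 10 had a median of 0.56 for regulatory T cell effector genes (9 of 16 higher, 1 lower; percentile 99.99), with Ebi3, an interleukin 35 subunit, 3.54-fold and Tnfrsf9 1.84-fold higher. Their interferon gamma response genes had a median of 0.65 (19 of 25 higher, none lower), with Tgtp1, 85.1% of whose 3' end is shared, 4.31-fold higher. Pdcd1 was 2.35-fold and Lag3 2.11-fold higher (log2 1.08, and 0.41 with each cell named on its own). The median log2 ratio of type I interferon response in Treg cells, day 10, was −0.69 (4 of 21 higher, 11 lower), and −0.05 with each cell named on its own. Dissociation and heat-shock genes of regulatory T cells had a median of −0.44 (2 of 23 higher, 10 lower; percentile 0.0). Gamma-delta T cells had a median of 0.65 for the interferon gamma response (18 of 26 higher, none lower), with Cxcl10 4.45-fold (log2 2.15, and 0.62 with doublets kept) and Iigp1 3.64-fold higher, and −0.46 for the cell cycle (8 of 18 lower, none higher; 0.29 with each cell named on its own).

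NK cells of day 10 held 3.70-fold more Gzmc and 3.35-fold more Gzmf in the knockout library (log2 1.75 for Gzmf, and 2.60 with mixed subclusters left out), but 4.80-fold less Ccl5 (log2 −2.26, and −1.62 as a mean over cells) and 2.85-fold less Gzma. Cytotoxicity had a median of −0.49 (3 of 18 higher, 8 lower; percentile 0.0). The type I interferon response had a median of −0.89 (19 of 28 lower, none higher), or −1.01 over the 12 members whose level in NK cells reached 0.1 of their highest in any class. Cell cycle genes had a median of 1.03 (27 of 34 higher, 1 lower; 1.94 in cells with at least 500 genes, 1.82 with each cell named on its own), hypoxia and glycolysis 0.75 (19 of 26 higher, 1 lower) and the dissociation and heat-shock response −0.23 (7 of 23 lower, none higher; percentile 0.21). Highest were Ccdc184 (7.57-fold), the ligand Tnfsf4 (7.27-fold) and Cd83 (7.01-fold), and Pdcd1 was 3.96-fold higher. Klf2 was 3.77-fold lower. Gm28727 (11.3-fold lower) and the processed pseudogene Gm5786 (8.88-fold; 84.5% of its 3' end shared) are uncertain. Cluster 10, with Gzma and Ccl5 among its leading genes, held 69.4% of control and 35.4% of knockout NK cells. Cluster 11, led by Gzmc, held 29.8% and 62.5%.

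Between days, neutrophils made up a smaller share on day 10 than on day 6 in control tumours (ratio 0.466, 0.434 to 0.499) and a larger one in knockout tumours (2.08, 1.95 to 2.21). NK cells were level in control (1.06, 0.996 to 1.14; 0.905 among cells other than neutrophils) and lower in knockout (0.397, 0.366 to 0.430). T cells had day 10 to day 6 ratios of 1.56 (1.47 to 1.66) and 1.08 (1.02 to 1.14), and macrophages or monocytes 1.41 (1.33 to 1.49) and 1.26 (1.2 to 1.33; 1.97 with cells thinned to 1000 UMIs).

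Type I interferon response genes of macrophages or monocytes were at a median of −0.08 on day 10 against day 6 in control (3 of 29 higher, 5 lower) and −1.15 in knockout (27 of 29 lower, none higher), those of T cells at 0.03 (2 of 29 higher, 4 lower; −0.26 as a mean over cells) and −0.86 (18 of 29 lower, none higher), and those of NK cells at 0.80 (17 of 28 higher, none lower) and 0.35 (11 of 27 higher, 4 lower). Cell cycle genes of macrophages or monocytes stood at −1.71 in control (32 of 34 lower) and 0.50 in knockout (17 of 34 higher). Means over cells gave −0.51 and 0.95, and knockout cells with at least 500 genes 0.30. Cluster 14 went from 15.3% to 51.7% of the class in control, cluster 8 from 23.7% to 51.4% in knockout. Hypoxia and glycolysis genes of neutrophils stood at 0.02 in control (7 of 25 higher, 2 lower; −0.42 relative to a shift of 0.44) and 1.09 in knockout (20 of 26 higher, none lower; 1.36 relative to a shift of −0.27). The granzyme Gzmf was higher on day 10 in T cells, at log2 ratios of 3.37 in control and 5.47 in knockout (4.34 and 6.51 as means over cells). In NK cells these were 2.11 and 6.89 (4.60 and 8.90). Cluster 11 went from 4.30% to 62.5% of knockout NK cells and cluster 25 from 5.32% to 32.1% of knockout T cells. Lower in T cells was the cytokine Il3 (45.6-fold in control, 65.0-fold in knockout; log2 −6.02 in knockout, and −4.20 as a mean over cells). Il5 was 4.71-fold higher in control T cells (log2 2.23), but stood at −0.77 with each cell named on its own, and Nrgn was 10.3-fold higher in knockout T cells (log2 3.36, and 4.03 as a mean over cells). In NK cells of control tumours Birc5 was 9.08-fold lower on day 10 (log2 −3.18, and −2.12 as a mean over cells).

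In macrophages or monocytes of control tumours, Mt2 was 5.93-fold and fibronectin, Fn1, 4.50-fold higher on day 10 and Ube2c 7.93-fold lower (log2 −2.99, and −1.19 as a mean over cells). In knockout tumours osteopontin, Spp1, was 9.75-fold and Mfge8 8.02-fold higher and Plac8 11.1-fold lower (log2 −3.47, and −4.36 with mixed subclusters left out). Dendritic cells of control tumours held 1 Cd207 UMI on day 6 and 100 on day 10 (log2 7.96, 5.45 to 13.28; 5.42 with doublets removed at the expected rate), 48.6-fold less Ccl17 and 5.56-fold less Iigp1. Those of knockout tumours held 13.1-fold more Il12b and 12.8-fold more Sult1a1 (log2 3.68, and 2.67 as a mean over cells), and 40.3-fold less Cd209e. In neutrophils, relative to the shifts above, Arfgef2 stood at 1.64, Sars at 1.33 and Hbegf at −2.56 in control, and Ciart at 3.18 (30.6% of its 3' end shared), Ffar2, a receptor of short-chain fatty acids, at −4.72 and 1110002J07Rik at −3.98 in knockout.

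Across genes, the knockout to control ratios of the 2 days had little in common in any class. Pearson correlations were 0.146 in macrophages or monocytes (11976 genes; Spearman 0.139) and 0.128 in dendritic cells (9533 genes; Spearman 0.119). They were negative in neutrophils (−0.166, 7126 genes; Spearman −0.231), T cells (−0.070, 10974 genes; Spearman −0.154) and NK cells (−0.028, 10445 genes; Spearman −0.074). CD8, CD4, regulatory and gamma-delta T cells had Pearson correlations of −0.179, −0.111, −0.102 and −0.123. With genes of at least 200 UMIs, the correlation was 0.220 in macrophages or monocytes, 0.198 in dendritic cells and −0.193 in CD4 T cells. These values are across genes, which are not independent replicates.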

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

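The test of doublet calls, the day 6 test with a higher minimum for the control library, the share of monocyte-like cells, and the sizes that the medians of a gene list had to reach on both days, were chosen only after the results were seen. Differences between days were not tested, and 1 library per group gives no spread to set them against.

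Knockout to control ratios of several shares stood on opposite sides of 1 on the 2 days. For neutrophils the ratio was 0.555 on day 6 and 2.47 on day 10, which is 4.46 times as high. T cells had 1.18 and 0.812 (0.690 times), dendritic cells 1.24 and 0.559 (0.452 times), mast cells or basophils 1.53 and 0.735 (0.481 times) and plasmacytoid dendritic cells 1.57 and 0.167 (0.106 times). Among cells other than neutrophils T cells had 1.03 and 1.01. Of the others only plasmacytoid dendritic cells had intervals on opposite sides of 1 (mast cells or basophils 1.33 and 0.910). Monocyte-like cells among macrophages, monocytes and dendritic cells, counted in named subclusters only, had 1.12 and 0.174 (0.155 times). Under 3 alternatives the day 6 value lay between 0.898 and 0.991 instead.

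On day 10 the knockout UMI minimum was raised by the largest ratio of median UMIs seen, 3.71 times in macrophages or monocytes, to 1853. The neutrophil share stayed higher, at 16.9% against 11.6% in control, a ratio of 1.46 (1.35 to 1.58). This argues against depth as the whole of the day 10 difference, but a part stays open, since medians were 1548 and 1613 UMIs in neutrophils and clusters also differed in macrophages or monocytes. The same step on day 6 (1.09 times, 0.548) could only lower the ratio and decides nothing. Raising the control library's minimum by 1.21 times, as in NK cells, to 603 UMIs gave 0.569 (0.533 to 0.606). This argues against a depth gap of that size as the whole difference, but neutrophil medians (1638.5 and 1303 UMIs) lay further apart. Keeping all doublets left a day 10 ratio of 2.52 (2.36 to 2.69), which argues against doublet calls. The tumour genotype and the number of mice behind each library stay open and were not tested, and sorting and library preparation cannot be separated from the groups.

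Several gene lists had medians (log2, knockout over control) of opposite sign on the 2 days. Inhibitory receptors were at −0.38 on day 6 and 0.44 on day 10 in T cells, a difference of 0.82, and at −0.46 and 0.32 in CD4 T cells, a difference of 0.78. In CD4 T cells, regulatory T cell effector genes stood at −0.27 and 0.53 (difference 0.79). CD8 T cells had cell cycle medians of −0.93 and 0.69 (difference 1.62) and naive and memory medians of 0.43 and −0.79 (difference −1.22), but on day 6 the first stood at −0.19 with doublets kept and −0.15 with each cell named on its own, and the second at −0.52 with doublets removed at the expected rate and −0.10 with each cell named on its own. Cell cycle genes of gamma-delta T cells stood at 0.53 and −0.46 (difference −0.99), but at −0.12 on day 6 in cells with at least 500 genes and at 0.29 on day 10 with each cell named on its own. Dissociation and heat-shock genes of neutrophils stood at 0.29 and −0.35 (difference −0.64), but at 0.06 and 0.05 relative to the scaling shift. Other neutrophil lists stood on opposite sides of 0 relative to that shift, the type I interferon response at −0.51 and 0.58, suppressive neutrophil genes at −0.37 and 0.68 and hypoxia and glycolysis at −0.49 and 1.31.

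Epithelial-like cells, which a CD45 sort should leave out, were 0.559% of control and 0.880% of knockout cells on day 6, and 3.21% and 4.89% on day 10 (3.15% and 3.67% with doublets kept).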

How the results depend on the processing

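The removal of doublets at the expected rate in every library, the shares of named immune cells, the omission of mixed subclusters, the restriction of lists to members expressed in the class, every alternative of a comparison between days, those for monocyte-like cells and for Cd274 in epithelial-like cells, and the omission of a cycling cluster were chosen only after the results were seen. No paired analysis was possible because there was 1 library per group and the labels carry no replicate numbers, so nothing here was set against a spread between libraries. A value is called moved where it left the counting interval, or for a list's median the order-statistic interval over its members, and reversed where its interval left out the value of no difference and its direction changed. A change of direction in a value whose interval held that value counts as stayed or moved. Monocyte-like cells are given as a share of macrophages, monocytes and dendritic cells, called myeloid cells here. Of 426 alternative values for 38 share ratios, 342 stayed within the interval, 75 moved and 9 reversed. Of 1000 for the list medians, 939 stayed, 55 moved and 6 reversed, of 80 for the CPM of Cd28, Cd274 and Pdcd1, 51 stayed and 29 moved, and all 9 correlations between days kept their sign and moved by less than 0.1 with genes of at least 200 UMIs. For 186 single genes, 968 of 1302 stayed, 327 moved and 7 reversed, and averaging over cells moved most, 103 genes. None of the share ratios moved among named immune cells or with mixed subclusters left out, and none of the list medians with members of at least 50 UMIs or members expressed in the class. Median-of-ratios scaling was not run for the correlations, since a constant cannot move one. Counts limit what can be said of rare cells, such as the 34 B cells of day 10 knockout. Values that moved or reversed follow by setting, and the cause was not tested.

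Among cells other than neutrophils, the share ratio of B cells was 0.758 on day 6. That of NK cells was 0.919 on day 6, 0.487 on day 10, and 0.905 and 0.480 between days in control and knockout. In the same order, that of T cells was 1.03, 1.01, 1.33 and 1.30 and that of macrophages or monocytes 0.993, 1.27, 1.2 and 1.53. That of dendritic cells was 1.08 on day 6 and 0.692 on day 10 and that of epithelial-like cells 1.89 on day 10. That of mast cells or basophils was 1.33 on day 6 and 0.910 on day 10.

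With each library clustered on its own, the share ratio of NK cells was 0.348 on day 10 and 0.345 between days in knockout, that of T cells was 0.897 on day 10 and that of macrophages or monocytes was 0.805 on day 6, 0.949 on day 10, 1.32 between days in control and 1.56 between days in knockout. That of neutrophils was 0.636 on day 6, 2.02 on day 10, 0.517 between days in control and 1.64 between days in knockout, that of CD8 T cells among T and NK cells was 1.91 on day 10 and that of monocyte-like cells among myeloid cells was 0.991 on day 6 and 0.356 on day 10.

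With each cell named on its own, the share ratio of NK cells was 0.978 between days in control and 0.339 between days in knockout, that of dendritic cells was 0.685 on day 10 and that of epithelial-like cells was 1.14 on day 10. That of macrophages or monocytes was 1.00 on day 6, 1.10 on day 10 and 1.61 between days in knockout, that of mast cells or basophils was 0.927 on day 10 and that of plasmacytoid dendritic cells was 0.297 on day 10. That of CD4 T cells among T and NK cells was 0.80 on day 10 and that of monocyte-like cells among myeloid cells was 0.293 on day 10. List medians (log2) of macrophages or monocytes were 0.66 on day 6 for cell cycle. Those of T cells were −0.28 on day 6 for type I interferon response and 0.015 on day 6 for cell cycle. Those of CD8 T cells were −0.10 on day 6 for naive and memory T cells, −0.086 on day 6 for T cell costimulation, −0.15 on day 6 for cell cycle and −0.43 on day 6 for type I interferon response. Those of regulatory T cells were −0.022 on day 6 for interferon gamma response and −0.34 on day 6 for type I interferon response. Those of NK cells were 1.82 on day 10 for cell cycle. Those of gamma-delta T cells were 1.08 on day 6 and 0.29 on day 10 for cell cycle. Those of B cells were −0.031 on day 6 for hypoxia and glycolysis. The log2 ratio of Gzmd in T cells was −4.00 on day 6 and that of Il5 in T cells was −0.77 between days in control.

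With cells thinned to 1000 UMIs, the share ratio of dendritic cells was 0.446 on day 10, that of macrophages or monocytes was 1.04 on day 6, 1.45 on day 10 and 1.97 between days in knockout and that of neutrophils was 0.490 on day 6 and 2.32 between days in knockout. That of NK cells among T and NK cells was 0.449 on day 10 and that of monocyte-like cells among myeloid cells was 0.115 on day 10.

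Without a cell filter, the share ratio of epithelial-like cells was 1.30 on day 10, that of macrophages or monocytes was 1.34 between days in knockout and that of CD8 T cells among T and NK cells was 0.597 on day 6 and 1.42 on day 10. That of monocyte-like cells among myeloid cells was 0.990 on day 6 and 0.308 on day 10.

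With doublets kept, the share ratio of epithelial-like cells was 1.16 on day 10, that of mast cells or basophils was 0.846 on day 10 and that of CD8 T cells among T and NK cells was 0.745 on day 6 and 1.81 on day 10. That of monocyte-like cells among myeloid cells was 0.319 on day 10. List medians (log2) of T cells were −0.26 on day 6 for type I interferon response and 0.053 on day 6 for cell cycle. Those of CD8 T cells were −0.19 on day 6 and 0.50 on day 10 for cell cycle and 0.47 on day 6 for type I interferon response. The CPM of Cd274 in neutrophils was 2926 and 2863 in control and knockout on day 6 and 1898 and 2713 on day 10. In T cells it was 156 in control day 6, 131 in control day 10 and 182 in knockout day 10. In epithelial-like cells it was 62.0 and 27.1 on day 10. That of Pdcd1 in CD8 T cells was 183 in knockout day 6 and 444 in control day 10 and that of Pdcd1 in NK cells was 10.7 in control day 6.

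With doublets removed at the expected rate in every library, the share ratio of epithelial-like cells was 1.21 on day 10, that of macrophages or monocytes was 1.34 between days in knockout and that of CD8 T cells among T and NK cells was 0.623 on day 6. That of monocyte-like cells among myeloid cells was 0.898 on day 6 and 0.328 on day 10. List medians (log2) of dendritic cells were −0.14 on day 6 for type I interferon response and 0.24 on day 6 for interferon gamma response. Those of T cells were 0.39 on day 6 and 1.09 on day 10 for cell cycle and −0.15 on day 6 for dissociation and heat-shock response. Those of CD8 T cells were −0.52 on day 6 for naive and memory T cells, −0.052 on day 6 for T cell costimulation, 0.89 on day 10 for cell cycle and −0.34 on day 6 and −2.23 on day 10 for type I interferon response. Those of regulatory T cells were 0.25 on day 6 for interferon gamma response. Those of macrophages or monocytes were 0.39 between days in knockout for cell cycle. The log2 ratio of Gzmd in T cells was −4.72 on day 6, that of Tcf7 in CD8 T cells was −0.81 on day 6 and that of Lag3 in CD8 T cells was 0.48 on day 6.

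In cells with at least 500 genes, the share ratio of macrophages or monocytes was 1.08 on day 6, 1.42 on day 10 and 1.79 between days in knockout and that of neutrophils was 0.489 on day 6, 2.30 on day 10, 0.502 between days in control and 2.36 between days in knockout. List medians (log2) of NK cells were 1.94 on day 10 for cell cycle. Those of gamma-delta T cells were −0.12 on day 6 for cell cycle. Those of macrophages or monocytes were 0.30 between days in knockout for cell cycle. Those of neutrophils were −0.092 between days in control for hypoxia and glycolysis. The log2 ratio of Gzmd in T cells was −5.55 on day 6. The CPM of Cd274 in neutrophils was 3101 and 2851 in control and knockout on day 6 and 1994 and 2775 on day 10. In macrophages or monocytes it was 535 and 545, then 261 and 291. In epithelial-like cells it was 23.2 in knockout day 10. That of Cd28 was 306 and 307 in T cells of control and knockout day 6 and 118 in NK cells of control day 6. That of Pdcd1 was 127 and 385 in CD8 T cells of control days 6 and 10. In NK cells it was 11.4 and 18.3 on day 6 and 184 in knockout day 10.

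At resolution 0.5, the share ratio of macrophages or monocytes was 1.31 between days in control, that of CD8 T cells among T and NK cells was 0.717 on day 6 and 1.82 on day 10 and that of CD4 T cells among T and NK cells was 0.851 on day 6 and 1.04 on day 10.

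At resolution 2.0, the share ratio of CD4 T cells among T and NK cells was 0.918 on day 6 and 1.03 on day 10, that of gamma-delta T cells among T and NK cells was 0.913 on day 6 and 1.35 on day 10 and that of NK cells among T and NK cells was 0.286 on day 10.

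Under median-of-ratios scaling, list medians (log2) of neutrophils were −0.51 on day 6 and 0.58 on day 10 for type I interferon response, −0.37 on day 6 and 0.68 on day 10 for suppressive neutrophil (PMN-MDSC) genes, −0.49 on day 6, 1.31 on day 10 and −0.42 between days in control for hypoxia and glycolysis and 0.055 on day 6 and 0.049 on day 10 for dissociation and heat-shock response.

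As means over cells of counts per 10000, list medians (log2) of macrophages or monocytes were −1.13 on day 10 for type I interferon response, 0.14 on day 10 for MHC class II presentation, 0.31 on day 6, 1.98 on day 10, −0.51 between days in control and 0.95 between days in knockout for cell cycle, 0.16 on day 6 and −0.34 on day 10 for dissociation and heat-shock response and 0.15 on day 10 for mitochondrial oxidative phosphorylation. Those of dendritic cells were 0.38 on day 10 for MHC class I presentation and 0.031 on day 6 for dissociation and heat-shock response. Those of T cells were −0.024 on day 6 for cell cycle and −0.26 between days in control for type I interferon response. Those of CD8 T cells were −0.36 on day 6 for type I interferon response. Those of regulatory T cells were 0.33 on day 10 for interferon gamma response. Those of gamma-delta T cells were 0.34 on day 6 for cell cycle. The log2 ratio of Gzmd in T cells was −0.37 on day 6.

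With the cycling macrophage cluster left out, the list median (log2) of macrophages or monocytes was 1.95 on day 10 for cell cycle.

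With mixed subclusters left out, the list median (log2) of macrophages or monocytes was −1.46 between days in knockout for type I interferon response.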

Other observations

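None of the tests in this part was chosen only after its result was seen, but the clusters and marker pairs described first were picked after their values were seen.

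Cells with the basophil protease Mcpt8, the transcription factor Gata2 and the cytokines Il4 and Il6 among their leading genes (cluster 0), and cells with the mast cell proteases Mcpt1, Mcpt2, Mcpt4 and Cma1 (cluster 24), lay in separate clusters that were joined in one class above. Cells of cluster 0 were 5.75% of control and 8.97% of knockout cells on day 6 and 1.95% of control cells on day 10. Counted without clusters, barcodes with at least 3 Mcpt8 UMIs were 491, 699, 131 and 28 (control and knockout on day 6, then on day 10), and those with at least 3 Mcpt4 UMIs were 42, 42, 257 and 434.

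An unnamed cluster led by Cd207 (langerin), Mfge8 and Epcam, genes of Langerhans-type dendritic cells, held 49 of its 51 cells in control day 10, where it was 0.521% of cells. Barcodes with both Cd207 and Epcam were 65 of 10441 there, 1 of 11469 in knockout day 6, 1 of 13366 in knockout day 10 and 0 of 12110 in control day 6, which allows up to 0.0248%. With 1 library per group, a cluster mostly of 1 library can be that library and not a type.

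Type I interferon response genes were lower in the day 10 knockout library in macrophages or monocytes, T cells and NK cells, but not in neutrophils (median 0.58 relative to the scaling shift, 0.22 to 0.84). Different macrophage or monocyte clusters in the 2 libraries were tested as a source by comparing within clusters, where the median over 4 clusters was −0.78, with 3 of them at or below −0.5 (−0.65, −0.91 and −0.96) and the fourth at −0.25. Free RNA in the control library could give at most 32.4% of the difference in NK cells, 11.9% in T cells and 4.06% in macrophages or monocytes. Both values argue against these as the whole of the pattern. A lower interferon response of these classes with the knockout tumours, and differences between mice or library preparations, stay open and were not tested.

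The predicted genes Gm28727 (T and NK cells) and Gm5786 (NK cells) were among those lowest in the day 10 knockout library, which led to tests of wider sets. Genes with near-identical 3' ends lay −0.11 from matched genes (median over 5 classes, range −0.17 to −0.04). This cannot decide whether shared reads were counted otherwise in that library, since some genes could gain reads that others lose. Processed pseudogenes lay −0.68 from matched protein-coding genes (median over 5 classes), at −1.07 in T cells, −1.0 in macrophages or monocytes and −0.68 in NK cells but −0.38 in dendritic cells and −0.27 in neutrophils. Without matching, day 6 gave 0.26, −0.01, 0.19, 0.21 and 0.37. Another way of counting pseudogene reads in the day 10 knockout library stays open. The classes differed and the counting software version for each library was not settled.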
